A study of Mus musculus with 12 samples.

How the data were processed

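The 12 libraries were polyA RNA sequencing of mouse tissue: 3 of non-tumour cortex, 3 of ependymomas driven by the ZFTA-RELA fusion (control tumours), 3 of such tumours with overexpression of human ETV5 and 3 with overexpression of human NPY. Per the labels, total RNA was extracted with a column kit and 300 ng went into stranded mRNA libraries that were sequenced as paired ends. Group and replicate number came from the sample titles. The labels do not say whether each replicate was a separate animal, so p-values measure the spread between these samples. In each group, libraries with high Xist and libraries with high Ddx3y both occurred, so a group held material from more than 1 animal.

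The authors deposited 2 tables of 24421 genes each. The first held cortex, control and ETV5 libraries, and the second held the control and NPY libraries. The submitters' processing notes name FastQC 0.11.7, MultiQC 1.6, STAR 2.5.0a, DESeq2 1.30.1 and the mouse build mm10, and the counting tool and gene annotation are not given in the sources used here. The deposited values were a normalized signal, not whole counts: every value was a whole multiple of 1 step per library within a tolerance of 0.01 read, which is read counts divided by 1 size factor per library. Division by that step gave back whole reads for 100% of values in each library. The control libraries had identical reads in both tables and different size factors, so levels were not compared between tables as deposited. In each of the tables, 27 symbols had turned into dates and 2 names occurred more than once, and 2 genes of the fixed lists were absent from the tables.

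Depth after recovery was 5962376 to 7444467 reads in cortex, 6266613 to 9443466 in control tumours, 6691146 to 11291057 in ETV5 tumours and 8214523 to 10481943 in NPY-labelled tumours. Levels are given as CPM (counts scaled to the recovered total of each library), as mean ± SD over 3 libraries. Where a group had 0 reads, the fold is a lower bound against 3 reads over the group. Where it had 1 to 3 reads, the ratio is given with its exact (Clopper-Pearson) 95% interval. Both cover counting error only. The genome positions come from the GENCODE M21 annotation of the same build, in which 299 of 302 named genes were found.

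The plan made before the data were examined named the edgeR quasi-likelihood test for counts and limma on log2(value + 1) for other values. As the deposited values were not counts, limma 3.58.1 was used, with a mean-variance trend and robust moderation, on the log2 of the deposited value plus 1, under R 4.3.3. Genes passed the edgeR filter (at least 10 reads in 3 libraries and 15 in total, scaled to library size). Tests were two-sided, and adjusted p-values are Benjamini-Hochberg values over the genes tested, called under 0.05. Group was the sole term. The comparisons were control tumours against cortex, ETV5 tumours against control tumours, NPY-labelled tumours against control tumours, and ETV5 against NPY-labelled tumours.

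The last of these departed from the plan, which allowed it for raw counts in both tables. It was run because whole reads were recovered and the controls had identical reads, on values re-scaled by median of ratios over the 9 tumour libraries. The ETV5 and NPY effects share their controls, which raises the overlap and the correlation of the effects. The correlation, and the overlap by limma, were therefore set beside 50 simulations with no effect. The replicate numbers were not treated as pairs in the main fits. Correlations across genes between libraries of the same number ranged from -0.41 to 0.37 after group means were removed. No range for unpaired libraries was set beside them, so pairing was neither shown nor excluded.

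The 39 gene lists (cell types, pathways, neuropeptides, serotonin genes) were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether a list's genes move on balance one way. In 5 pairs of a list and a comparison a member had 0 reads in a group, and setting such members at their bound moved no list median. The genes named in the text followed a rule of the same date. It took (a) Etv5, Npy, Rela, Zfta and the serotonin and neuropeptide genes; (b) the 10 largest called rises and falls with a mean of at least 5 CPM and no overlap between groups, without predicted symbols; and (c) up to 3 called members per direction of each list, or its 2 most abundant members where fewer than 2 were called. Genes outside it are marked as chosen after their values were seen. Not each gene that the rule allows is reported here. The share of cortical tissue in a library was measured as the median, over the list of cortical excitatory neuron genes, of its level relative to the mean of the cortex libraries.

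The tests were tried on simulated data with 200 changed genes, 5 times per comparison. Of genes changed 2-fold, limma recovered 52.4% in the tumour and cortex design, 2.4% in the ETV5 design, 6.8% in the NPY design and 5.2% in the design of ETV5 against NPY. Of genes changed 4-fold it recovered 90.6%, 52.6%, 64.6% and 59.4%. A list raised on purpose was called in 5 of 5 simulations in each design. Genes were drawn independently there and camera used the preset correlation. The simulations therefore do not test calls in lists whose genes vary together.

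The alternatives chosen before the data were examined were other scaling, other filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, the spread over other groups, abundant genes removed, the library code prefix as a covariate, a fold threshold, the other set tests, and each replicate left out. Added after the data were seen were edgeR 4.0.16 on the recovered reads, TMM scaling, other pseudocounts and the cortex share as a covariate. All NPY libraries and ETV5 replicate 3 carry the code prefix EC and the others carry DS, so the prefix and the NPY group are nearly confounded. Whether replicate pairs were duplicates was checked with a chi-square test of their reads: the value per degree of freedom ranged from 6.52 to 66.8, so every pair differed by more than sampling noise.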

Results

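Gene expression was measured by RNA sequencing in 12 mouse libraries from 4 groups of 3: non-tumour cortex, ependymomas driven by the ZFTA-RELA fusion (a chimaeric transcription regulator found in ependymoma), and the same tumour model with overexpression of human ETV5, an ETS family transcription factor, or of human NPY, the neuropeptide Y precursor. The title of the series concerns serotonylation of histones and neurodevelopmental pathways in ependymoma. Depth ranged from 5962376 reads in cortex replicate 2 to 11291057 in ETV5 replicate 3. Levels are CPM, as mean ± SD with n = 3 libraries per group, from reads recovered from the deposited normalized signal. Log2 fold changes and their standard errors (SE) come from limma. Replicates correlated, across genes that are not independent of each other, at r = 0.981 to 0.983 in cortex, 0.939 to 0.965 in control tumours, 0.889 to 0.936 in ETV5 tumours and 0.924 to 0.965 in NPY-labelled tumours.

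The 2 overexpressed genes were examined first, at their mouse loci. The transgenes were human, so reads counted at the mouse genes are no direct measure of them. Mouse Etv5 (chromosome 16, 22381309 to 22439719, minus strand, protein coding, mm10) stood at 106, 144 and 109 CPM in the cortex libraries, 264, 322 and 299.5 in control tumours, 407, 474 and 401 in ETV5 tumours and 346, 325.5 and 251 in NPY-labelled tumours. Its level in ETV5 tumours lay above each control library, with a log2 fold change of 0.52 (SE 0.16) that did not pass (adjusted p = 0.732). Non-overlap of this kind arises by chance in 10% of genes for 3 against 3. Mouse Npy (chromosome 6, 49822710 to 49829507, plus strand, protein coding) stood at 78.4, 128 and 129 CPM in cortex, 27.2, 21.5 and 46.1 in control tumours, 1.44, 18.5 and 4.69 in ETV5 tumours and 5.59, 2.19 and 15.9 in NPY-labelled tumours. Neither tumour set with an added gene passed for Npy (log2 fold change -2.54, adjusted p = 0.732 with ETV5, and -2.25, adjusted p = 0.113 with NPY). DESeq2 called the second of these, as did limma without NPY replicate 3 (log2 fold change -2.96, against -1.58 without NPY replicate 2). With ETV5 the Npy value was -3.45 without ETV5 replicate 2 and -1.66 without ETV5 replicate 1. As mouse Npy cannot show human NPY, these tumours are called NPY-labelled. The name ETV5 tumours likewise follows the label, as reads at mouse Etv5 cannot show human ETV5.

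**Figure D1:**
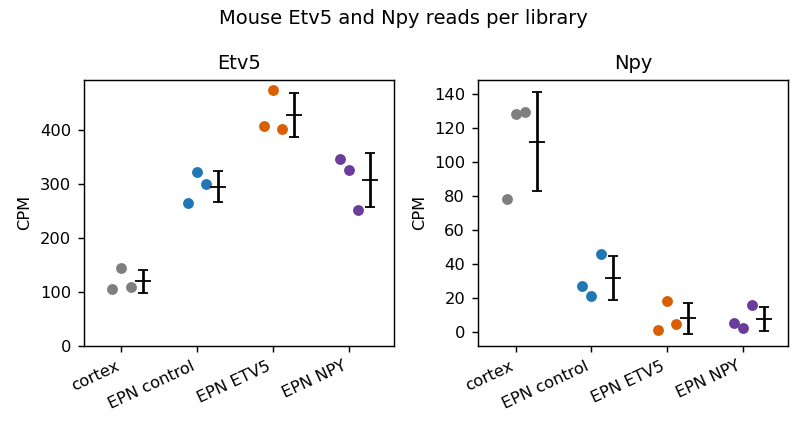
Mouse Etv5 and Npy levels in CPM on linear axes in each of the 12 libraries, by group; coloured points are libraries, and black marks with bars are the mean and SD (n = 3). Etv5 lies between 401 and 474 CPM in the ETV5 tumours, and Npy lies between 78.4 and 129 CPM in cortex.

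Control tumours were compared with cortex to ask how the tumour differs from non-tumour cortex. The tumours held far more transcript of proliferation genes and of some neural stem cell genes. Vim, an intermediate filament of radial glia, rose 44.2-fold, from 39.6 ± 2.02 to 1981 ± 165 CPM, and Nes, the nestin gene, rose 21.5-fold, from 9.69 ± 0.693 to 238 ± 26.3 CPM. Cdk1, the mitotic cyclin-dependent kinase, rose 48.4-fold to 109 ± 19.7 CPM, and Mcm3, a subunit of the replicative helicase, rose 20.8-fold to 95.6 ± 21.1 CPM. The 20 measured mitosis genes and the 20 measured DNA replication genes each rose, also when adjusted over the list alone (median log2 fold changes 4.65 and 3.34, camera adjusted p = 1.1e-08 and 5.1e-08). Each of these list calls had an adjusted p = 0.397 with an estimated correlation. Of 17 radial glia and neural stem cell genes, 10 rose and 6 fell, over all genes and adjusted over the list alone, and the list was not called (camera adjusted p = 0.251). In total limma called 10521 of 14621 tested genes, 5225 higher and 5296 lower, of which 7137 differed at least 2-fold. Camera called 22 of 39 lists, 11 higher and 11 lower, and with an estimated correlation the called lists had adjusted p-values between 0.397 and 0.424, so 0 were called. Fry called 35 lists, among them these 22. The test with an estimated correlation called 0 lists in each of the 4 comparisons, even where all 20 mitosis genes were called singly. It was not tried on simulated data, so a list that it did not call is not thereby shown to be unchanged.

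Genes tied to this tumour type were examined next. Reads at both fusion partners were higher: Rela (chromosome 19, 5637483 to 5648130), the p65 subunit of NF-kB, rose 4.05-fold to 87.4 ± 15.2 CPM, and Zfta, listed under the symbol 2700081O15Rik (chromosome 19, 7417625 to 7425904), rose 4.80-fold to 224 ± 33.3 CPM. Gene counts cannot tell the endogenous genes from the fusion transcript, so a rise of the endogenous genes is not shown. Of 16 genes reported for this tumour type in other work, 13 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.000575, and adjusted p = 0.397 with an estimated correlation). Igf2, a fetal growth factor, rose 25.8-fold to 4597 ± 1606 CPM, Runx1, a transcription factor, rose 18.4-fold, and Cdk6, a G1 kinase, rose 15.4-fold. The 2 that fell were L1cam, a neuronal adhesion molecule, from 131 ± 18.2 to 10.8 ± 4.64 CPM, and Fgfr3, a growth factor receptor, from 159 ± 19.3 to 56.3 ± 5.28 CPM. NF-kB targets rose in 16 of 18 measured members and fell in 1, with 17 and 1 adjusted over the list alone (median log2 fold change 3.42, camera adjusted p = 6.2e-05, and adjusted p = 0.397 with an estimated correlation). Some of the largest rises were in genes nearly silent in cortex. Nr5a1, a nuclear receptor of steroid-forming tissue (chromosome 2, 38692656 to 38714542), reached 299 ± 70.5 CPM against 0 reads in cortex, at least 2002-fold higher. Akr1cl, an aldo-keto reductase, reached 205 ± 45.1 CPM against 0 reads, at least 1362-fold higher. Wt1, a zinc finger transcription factor of mesothelium and kidney, reached 154 ± 52.1 CPM against 3 reads in cortex, a ratio of 1024 (95% interval 350.2 to 4969). Tnnt3, a fast muscle troponin, reached 392 ± 71.7 CPM.

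Neuronal, synaptic and myelin genes were low in the control tumours. Snap25, a protein of synaptic vesicle fusion, fell from 2209 ± 237 to 167 ± 125 CPM, and Gad2, a GABA-synthesizing enzyme, fell from 207 ± 70.7 to 12.6 ± 10.1 CPM. Rims1, an active zone scaffold, fell 27.2-fold, and Grin2b, an NMDA receptor subunit, fell 42.1-fold. The 16 pan-neuronal, 13 excitatory, 14 inhibitory, 18 presynaptic and 22 glutamate and GABA receptor genes measured each fell, also when adjusted over the list alone. The medians of these lists lay between -3.88 and -3.36 on the log2 scale (camera adjusted p at most 3.2e-05, and adjusted p = 0.397 with an estimated correlation in each). Mature oligodendrocyte and myelin genes fell in 13 of 14, also adjusted over the list alone (camera adjusted p = 0.000575, and adjusted p = 0.397 with an estimated correlation), with Mog, a myelin glycoprotein, 10.8-fold and Mal, a myelin proteolipid, 13.5-fold lower. The exception was Trf, the transferrin gene, which rose from 215 ± 35.4 to 1716 ± 417 CPM. The cortex share, set by the excitatory neuron genes, was 98.6 ± 9.52% in cortex and 9.85 ± 4.20% in control tumours (6.72, 8.20 and 14.6%).

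Astrocyte genes split. Gfap, the astrocyte filament, rose 6.23-fold to 2082 ± 455 CPM and Clu, the clusterin gene, rose 3.51-fold, whereas Slc1a2, the main glutamate transporter, fell 7.61-fold to 592 ± 59.7 CPM and Aldoc, a glycolytic enzyme of astrocytes, fell 5.05-fold. Of 14 measured astrocyte genes 2 rose and 10 fell, over all genes and adjusted over the list alone, and the list was not called (camera adjusted p = 0.0507). Motile cilia genes, which mark normal ependyma, fell in 13 of 16 and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0197, and adjusted p = 0.424 with an estimated correlation). Drc1, of the dynein regulatory complex, fell (log2 fold change -3.39, SE 0.30), and the 1 that rose was Hydin, a central pair protein, by 21.5-fold. Choroid plexus genes fell in 11 of 13 and rose in 1, also adjusted over the list alone (camera adjusted p = 0.00483, and adjusted p = 0.397 with an estimated correlation), and Ttr, the transthyretin gene made by choroid plexus, stood at 1.01 ± 0.865 CPM against 1030.1 ± 437 in cortex.

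Interferon, antigen presentation, macrophage and matrix genes were high in the tumours. Cd74, the class II invariant chain, rose from 3.01 ± 0.601 to 876 ± 583 CPM, Irf7, an interferon regulatory factor, from 0.929 ± 0.572 to 219 ± 87.3, and C3, the central complement component, from 0.661 ± 0.320 to 713 ± 261. The 20 interferon response genes measured and 15 of 16 antigen presentation genes rose, also adjusted over the list alone (camera adjusted p = 3.8e-08 and 3.1e-06, and adjusted p = 0.397 with an estimated correlation in both). Microglia and macrophage genes rose in 16 of 18 and fell in 2, also adjusted over the list alone (camera adjusted p = 3.1e-05, and adjusted p = 0.397 with an estimated correlation). C1qc, a complement subunit made by microglia, rose 17.0-fold, and P2ry12, a purinergic receptor of resting microglia, fell 1.87-fold. Extracellular matrix genes rose in 15 of 16, also adjusted over the list alone (camera adjusted p = 2.1e-06, and adjusted p = 0.397 with an estimated correlation), with Col1a1, a fibrillar collagen, at 1668 ± 549 against 14.3 ± 3.31 CPM. Some other immune and stromal lists were not called: homeostatic microglia (6 of 10 rose and 2 fell, camera adjusted p = 0.0746), lymphocytes (2 of 4 rose, 0.231), pericytes and smooth muscle (7 of 12 rose and 1 fell, 0.0851) and meninges (4 of 9 rose and 4 fell, 0.915). Adjusted over the list alone, 6, 2, 9 and 4 rose and 2, 0, 2 and 4 fell (adjusted p = 0.397, 0.397, 0.430 and 0.918 with an estimated correlation).

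Serotonin genes and neuropeptides were the lists closest to the question of the series. Of 17 measured serotonin genes 12 fell and 1 rose, over all genes and adjusted over the list alone (median log2 fold change -2.39, camera adjusted p = 0.00636, and adjusted p = 0.397 with an estimated correlation). The 1 that rose was Tgm2, the transglutaminase that attaches serotonin to proteins, which rose 34.1-fold to 428 ± 61.3 CPM. Among those that fell were the receptors Htr1a (26.2-fold) and Htr2c (28.4-fold), and Maoa, which degrades serotonin, fell 1.49-fold to 34.6 ± 4.79 CPM. Of 18 measured neuropeptide genes 15 fell and 1 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.00121, and adjusted p = 0.397 with an estimated correlation). Tac1, the substance P precursor, fell 73.3-fold, Vip, a peptide of interneurons, 31.2-fold, Sst, the somatostatin gene, 11.7-fold and Npy 4.09-fold. Gal, the galanin gene, rose from 0.547 ± 0.367 to 4.17 ± 3.06 CPM. The Npy call ended in the fit with the library code prefix, at the same log2 fold change (-2.03). Cortex and control libraries share 1 prefix, and that fit took its spread from the ETV5 libraries as well. Etv5 rose 2.20-fold (log2 fold change 1.14, SE 0.16, adjusted p = 0.000243), and each tumour library lay above each cortex library.

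**Figure D2:**
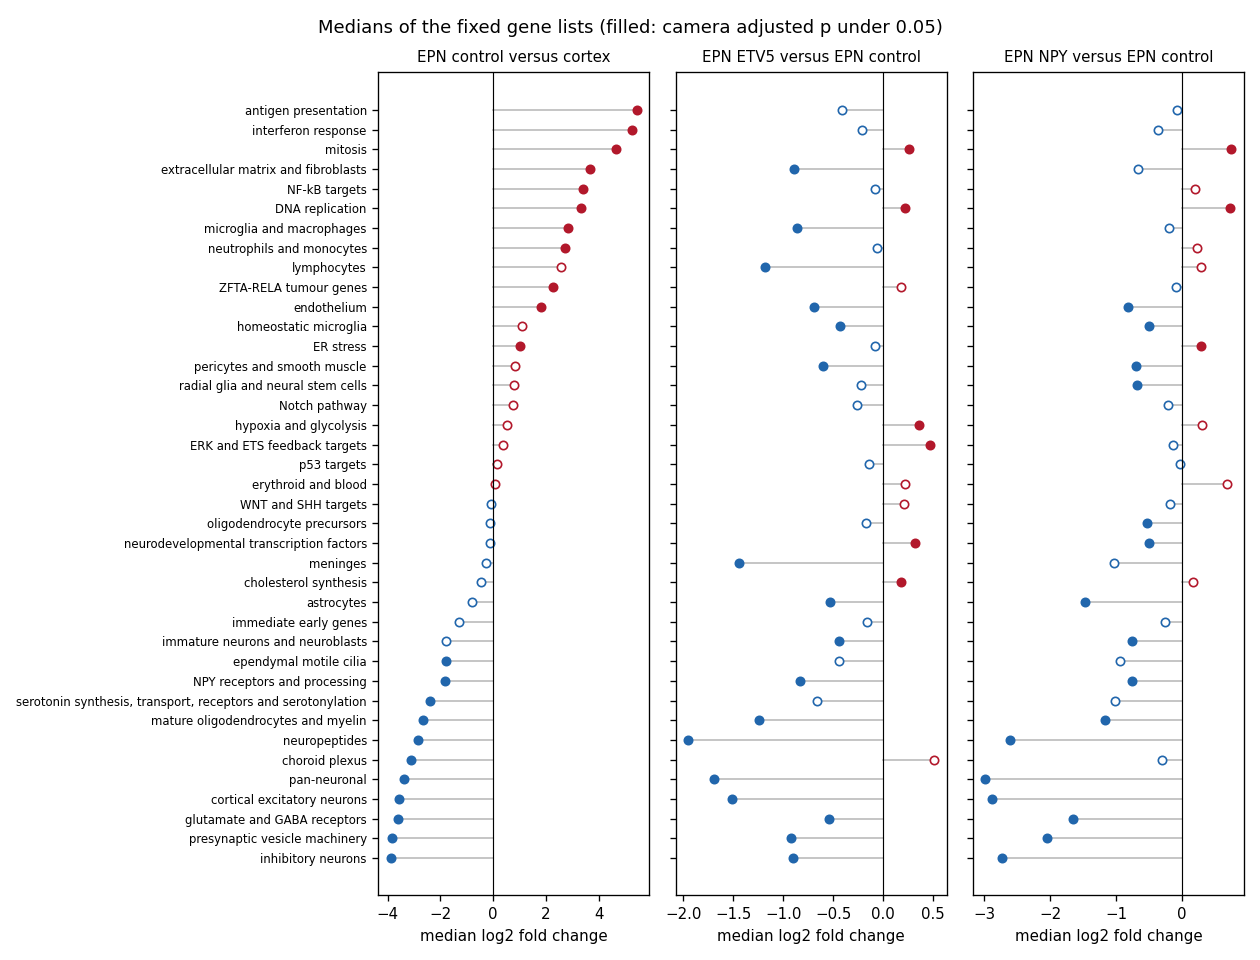
Median log2 fold change of each of the 39 gene lists (y axis) in the comparisons of control tumours with cortex, ETV5 with control tumours and NPY-labelled with control tumours, each with its own x axis; filled points were called by camera (preset correlation), and red and blue points lie above and below 0. Inhibitory neuron genes have the lowest median against cortex (-3.88), and pan-neuronal genes have a median of -1.69 with ETV5 and -2.99 with NPY.

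ETV5 tumours were compared with control tumours to ask what the added factor alters. At this depth and spread 0 of 14382 genes passed with limma (lowest adjusted p = 0.732), while 944 had an unadjusted p under 0.05. The edgeR and limma-voom tests also called 0, and DESeq2 called 76, 17 higher and 59 lower. The named genes did not pass. Vim stood at 1389 ± 38.1 against 1981 ± 165 CPM in controls, Mbp, a myelin protein, at 569 ± 377 against 1590.5 ± 625, Snap25 at 71.4 ± 77.7 against 167 ± 125 and Cx3cr1, the fractalkine receptor of microglia, at 166 ± 59.9 against 336 ± 79.6. Dusp6, a phosphatase induced by ERK signalling, stood at 150.2 ± 77.7 against 102 ± 7.26 CPM. Rela stood at 98.1 ± 11.2 against 87.4 ± 15.2 CPM. The cortex share of the ETV5 tumours was 0.695, 9.02 and 2.77%, against 6.72, 8.20 and 14.6% in controls.

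As sets, 23 of 39 lists were called by camera between ETV5 and control tumours, 6 higher and 17 lower, with 0 members of any list called over all genes. With an estimated correlation 0 were called, and the adjusted p-values of these 23 lay between 0.415 and 0.684. Fry also called 0 (lowest adjusted p = 0.338). ERK and ETS feedback targets, the group nearest to an ETS factor, had positive values in 14 of 17 members (median log2 fold change 0.47, camera adjusted p = 0.000299, and adjusted p = 0.415 with an estimated correlation), with 0 called adjusted over the list alone. DNA replication genes had positive values in 20 of 20 (median 0.21) and mitosis genes in 19 of 20 (median 0.25), with 0 called adjusted over the list alone in either (camera adjusted p = 0.000141 and 0.000165, and adjusted p = 0.415 and 0.438 with an estimated correlation). Mki67, a proliferation marker, stood at 251 ± 68.8 against 179 ± 43.2 CPM. The make-up of these libraries differed too. Rn45s, the ribosomal RNA precursor, stood at 1409.5, 1079 and 5503.5 CPM in ETV5 replicates 1, 2 and 3, against 618 to 754 in controls. Lars2, a mitochondrial tRNA synthetase, stood at 303, 305 and 791 CPM in the same order, against 183 to 284. Both upper values came from replicate 3, the ETV5 library with the code prefix EC. The share of ribosomal protein genes and Malat1, a nuclear non-coding RNA, overlapped between the groups. Rn45s, Lars2 and Malat1 were chosen here after their values were seen. Pan-neuronal genes were negative in 16 of 16 (median -1.69), presynaptic genes in 18 of 18 (median -0.93) and myelin genes in 13 of 13 (median -1.25), with 0 called adjusted over the list alone (camera adjusted p at most 1.5e-05, and adjusted p = 0.415 with an estimated correlation in each). With the cortex share in the fit, camera called 7 lists, and the pan-neuronal median was -0.11. The share is itself set by excitatory neuron genes, so that fit cannot tell less cortical tissue from another loss of neuronal transcripts. Neuropeptides were negative in 11 of 12 (median -1.95, camera adjusted p = 0.000272, and adjusted p = 0.415 with an estimated correlation), with 0 called adjusted over the list alone. Sst stood at 6.49 ± 7.99 against 19.6 ± 11.4 CPM, and Gal at 0.618 ± 0.504 against 4.17 ± 3.06. Vessel and stromal genes were mostly negative: matrix genes in 15 of 16, endothelial genes in 13 of 14 and meningeal genes in 7 of 8, with 0, 3 and 3 called lower adjusted over the list alone (camera adjusted p at most 0.000382, and adjusted p = 0.415 with an estimated correlation in each). Pdgfrb, a receptor of pericytes, stood at 189.9 ± 43.7 against 291 ± 26.4 CPM, and Ogn, a matrix proteoglycan, at 39.3 ± 28.2 against 91.0 ± 22.6. The serotonin list was not called (camera adjusted p = 0.0666), with Tgm2 at 304 ± 193 against 428 ± 61.3 CPM and Maoa at a log2 fold change of -0.72 (SE 0.19, adjusted p = 0.732). Without ETV5 replicate 1, the camera count was 16 lists, and without ETV5 replicate 2 it was 28.

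NPY-labelled tumours were compared with control tumours to ask what overexpression of the peptide alters. Many neuronal and synaptic genes were far lower in the NPY-labelled tumours, some astrocyte genes were lower, and some proliferation genes were higher. Snap25 fell 23.1-fold to 5.80 ± 1.54 CPM and Syt1, the calcium sensor of vesicle release, fell 17.0-fold from 111 ± 61.4 to 5.67 ± 1.54 CPM. Slc17a7, the vesicular glutamate transporter of cortical neurons, fell 18.7-fold, Rph3a, a vesicle protein, fell 21.4-fold and Hpca, the hippocalcin gene, fell 26.3-fold. Neurod6, a transcription factor of excitatory neurons, had 0 reads in the NPY-labelled tumours against 3.76 ± 2.71 CPM, at least 30.4-fold lower. Pan-neuronal genes fell in 10 of 16, presynaptic genes in 12 of 18, excitatory neuron genes in 7 of 13, inhibitory neuron genes in 4 of 9 and receptor genes in 9 of 20. Adjusted over the list alone, 15, 17, 9, 6 and 15 fell. The medians were -2.99, -2.06, -2.89, -2.74 and -1.66 (camera adjusted p at most 0.000206, and adjusted p = 0.355 to 0.389 with an estimated correlation). The cortex share was 1.16 ± 0.633% in the NPY-labelled tumours (0.770, 1.89 and 0.814%) and 9.85 ± 4.20% in controls.

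Some astrocyte, radial glia, oligodendrocyte precursor and endothelial genes fell too. Slc1a2 fell 6.70-fold to 90.9 ± 49.4 CPM, Gjb6, an astrocyte connexin, fell 9.72-fold, and Slc1a3, the glutamate transporter of radial glia and astrocytes, fell 5.56-fold to 109 ± 76.9 CPM. Of 14 astrocyte genes 6 fell, or 10 adjusted over the list alone (median -1.48, camera adjusted p = 5.5e-08, and adjusted p = 0.355 with an estimated correlation). Of 17 radial glia and neural stem cell genes 3 fell, or 7 adjusted over the list alone (camera adjusted p = 0.00325, and adjusted p = 0.355 with an estimated correlation), among them Fabp7, a fatty acid binding protein of radial glia, at 37.0 ± 13.6 against 96.1 ± 16.2 CPM. Of 10 oligodendrocyte precursor genes 3 fell, or 4 adjusted over the list alone (camera adjusted p = 0.00525, and adjusted p = 0.389 with an estimated correlation), with Bcas1 at 98.9 ± 7.97 against 272 ± 20.3 CPM and Gpr17, a receptor of maturing precursors, at 37.0 ± 3.19 against 87.0 ± 22.2. Of 18 neurodevelopmental transcription factors 2 fell, among them Emx1, a homeobox gene of the cortex (6.56-fold), and 7 fell adjusted over the list alone (camera adjusted p = 0.00707, and adjusted p = 0.355 with an estimated correlation). Of 13 myelin genes 1 fell, or 7 adjusted over the list alone (camera adjusted p = 0.00015, and adjusted p = 0.389 with an estimated correlation). Of 14 endothelial genes 2 fell, also adjusted over the list alone (camera adjusted p = 0.000368, and adjusted p = 0.389 with an estimated correlation): Slco1a4, a transporter of brain vessels, 6.23-fold and Abcb1a, a drug efflux pump, 2.02-fold.

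Neuropeptide genes fell in 4 of 10, or 8 adjusted over the list alone (median -2.61, camera adjusted p = 4.6e-06, and adjusted p = 0.355 with an estimated correlation). Cck, the cholecystokinin gene, fell 13.1-fold, Sst fell 15.3-fold, and Gal fell 9.23-fold from 4.17 ± 3.06 CPM. Pnoc, the nociceptin precursor, fell to 3 reads in the NPY-labelled tumours against 56 in controls, a ratio of 0.0493 (95% interval 0.00987 to 0.152). Npy2r, a receptor of NPY, fell 8.63-fold to 0.338 ± 0.129 CPM, and Pcsk2, a convertase that processes peptide precursors, fell 16.8-fold. These were the 2 of 7 NPY receptor and processing genes that fell, or 3 adjusted over the list alone (camera adjusted p = 0.0094, and adjusted p = 0.389 with an estimated correlation). Of 8 measured serotonin genes 1 fell, Htr3a, an ion channel receptor, at 0.379 ± 0.100 against 3.75 ± 1.85 CPM. Adjusted over the list alone, 1 rose and 3 fell, and the list was not called (camera adjusted p = 0.0749). Tgm2 stood at 558 ± 138 against 428 ± 61.3 CPM, Maoa at 16.6 ± 4.86 against 34.6 ± 4.79 and Ddc, which makes serotonin from its precursor, at 17.6 ± 3.51 against 9.36 ± 2.41, and these did not pass.

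DNA replication and mitosis genes formed 2 of the 3 lists called higher. Gins2, a subunit of the replicative helicase, rose 2.13-fold to 40.6 ± 1.99 CPM, Pcna, the polymerase clamp, rose 1.66-fold to 266 ± 30.7, and Kif11, a spindle motor, rose 2.21-fold to 108 ± 22.3. Of 20 replication genes 3 rose, or 18 adjusted over the list alone, and of 20 mitosis genes 2 rose, or 19 adjusted over the list alone (medians 0.72 and 0.75, camera adjusted p = 7.7e-10 and 2.5e-10, and adjusted p = 0.355 and 0.389 with an estimated correlation). The other list called higher, ER stress, had positive values in 12 of 14 members, with 0 called, also adjusted over the list alone (median 0.28, camera adjusted p = 0.0403, and adjusted p = 0.389 with an estimated correlation). Ptch1, a receptor and target of hedgehog signalling, rose 2.02-fold, and Nrarp, a Notch target, rose 2.08-fold, each as the 1 called member of its list, also adjusted over the list alone. Ifi44l, an interferon-induced gene (chromosome 3, 151758737 to 151762892, minus strand, annotated with an error of the reference genome), had 0 reads in controls and 16.4 ± 5.31 CPM in NPY-labelled tumours, at least 136-fold higher. H2-T3, a non-classical MHC class I gene (chromosome 17, 36185572 to 36190287), rose from 0.770 ± 0.564 to 11.5 ± 4.18 CPM and H2-Eb1, an MHC class II gene (chromosome 17, 34305867 to 34316674), from 6.82 ± 5.89 to 183 ± 151. H2-Eb1 was the 1 of 16 antigen presentation genes that rose, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.917, with a median of -0.07 and a mean of 0.23). Dmrt1, a transcription factor of the gonads, rose 3.28-fold to 81.2 ± 18.9 CPM. Rn45s, the ribosomal RNA precursor, rose 5.03-fold to 3898 ± 2240.5 CPM, in libraries made from polyA RNA. Malat1, a nuclear non-coding RNA, fell (45.9 to 65.9 CPM against 146 to 163 in controls), and Lars2, a mitochondrial tRNA synthetase, rose (446 to 805 CPM against 183 to 284), both chosen after their values were seen. Ribosomal protein genes held 4.55 to 6.25% of reads in NPY-labelled tumours and 3.87 to 4.25% in controls, so the make-up of these libraries differed along with the lists called higher.

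**Figure D3:**
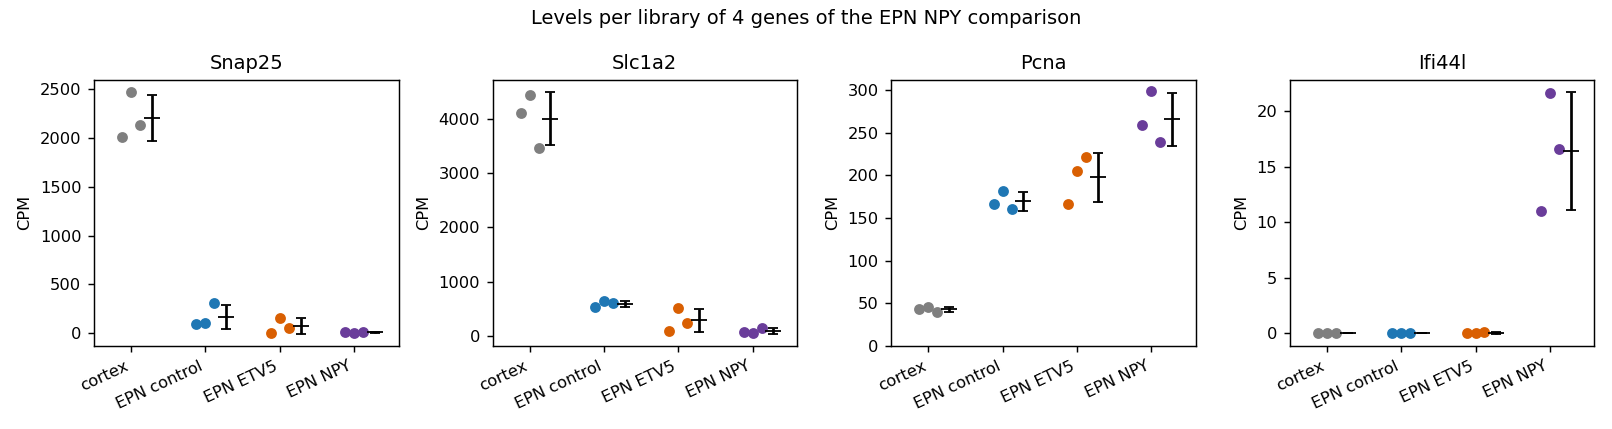
Levels in CPM on linear axes of Snap25, Slc1a2, Pcna and Ifi44l in each library by group; coloured points are libraries, and black marks with bars are the mean and SD (n = 3). In the NPY-labelled tumours Snap25 averages 5.80 CPM against 167 in controls, Pcna averages 266 against 169, and Ifi44l lies between 11.1 and 21.7 CPM.

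In this comparison limma called 727 of 14425 genes, 105 higher and 622 lower, and 3389 had an unadjusted p under 0.05. Camera called 19 lists, 3 higher and 16 lower, of which 0 were called with an estimated correlation (adjusted p = 0.355 to 0.410), and fry called 11. The gene count fell whenever a library was left out. It was 138 without control replicate 1, 1 without control replicate 2 (Sez6, a neuronal gene chosen after its value was seen), 78 without control replicate 3 and 125 without NPY replicate 1. The highest of these counts was 571, without NPY replicate 2. Without control replicate 2, 2701 genes still had an unadjusted p under 0.05 by limma. Each such fit has fewer libraries, so lost power and dependence on the library left out cannot be told apart. DESeq2 called 1833, 606 higher and 1227 lower, and the spread over all groups gave 1128. With either the library code prefix or the cortex share in the fit limma called 0 (edgeR on the recovered reads called 685 with neither term). The cortex share did not overlap between the groups (0.770 to 1.89% in NPY-labelled and 6.72 to 14.6% in control tumours). A fit with the share therefore cannot separate it from the group, and the loss of calls decides nothing. With the prefix, the median log2 fold change of the genes called lower went from -2.25 to -2.57 and their median SE from 0.348 to 1.08.

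ETV5 and NPY-labelled tumours were compared directly to ask whether the 2 effects differ. Limma called 1 of 14648 genes, and 1357 had an unadjusted p under 0.05. The gene was Ifi44l, with 1 read in the ETV5 tumours and 443 in the NPY-labelled tumours, a ratio of 0.00237 (95% interval 6e-05 to 0.0133), and the ETV5 tumours lay below in each library (adjusted p = 0.00862). Over the settings tried, the adjusted p of Ifi44l ranged from 6.2e-08 to 0.635. Etv5 stood at 427 ± 40.4 against 308 ± 49.8 CPM (log2 fold change 0.42, SE 0.16, adjusted p = 0.519) and Npy at 8.22 ± 9.07 against 7.90 ± 7.16 CPM. Nfib, a transcription factor of gliogenesis, stood at 174 ± 100.1 against 56.5 ± 9.34 CPM, Vamp2, a vesicle SNARE, at 90.2 ± 34.6 against 39.3 ± 0.839, and Tgm2 at 304 ± 193 against 558 ± 138. The edgeR test called 0 genes and DESeq2 called 173. The count was 88 without ETV5 replicate 1, 3 without NPY replicate 1 (Ifi44l, Serpina3b and Slit3, the last 2 chosen after their values were seen) and 0 without NPY replicate 2 or without NPY replicate 3. Camera called 16 lists, 10 higher and 6 lower in ETV5 tumours, with 0 called at an estimated correlation (adjusted p = 0.425 to 0.579) and 0 by fry.

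The overlap of the ETV5 and NPY effects against the shared controls was 0 genes by limma, since 0 genes were called with ETV5 (944 and 3389 genes had an unadjusted p under 0.05). By DESeq2, 10 genes were higher in both and 22 were lower in both. The shared controls raise such counts, and their size with no effect was not simulated for DESeq2. Across 14236 genes, which are not independent of each other, the log2 fold changes correlated at r = 0.688. Simulations with no effect and with shared simulated controls gave r = 0.502 on average, from 0.477 to 0.528 in 50 simulations. On average limma called 0 genes in both there. Genes were drawn independently in these simulations, so their range is no bound for real genes that vary together. Whether 0.688 exceeds what shared controls alone give was therefore not settled. The control tumours were 3 and could not be divided between the comparisons.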

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

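The tests below of MHC and interferon genes were chosen after the results were seen, and the splits of the libraries were planned. Results are listed here because they were called in the direct test of ETV5 against NPY-labelled tumours, though not by each method tried. By gene, limma called Ifi44l, at a log2 fold change of -6.84 for ETV5 against NPY-labelled tumours (1 read against 443). That fitted value depends on the pseudocount. By gene list, with camera at a preset correlation, the medians were higher in ETV5 tumours for radial glia (0.46), astrocytes (1.25), pan-neuronal genes (1.17), excitatory neurons (1.32), inhibitory neurons (1.04), presynaptic genes (1.15), glutamate and GABA receptors (1.04), neurodevelopmental transcription factors (0.81), neuropeptides (0.92) and ERK and ETS feedback targets (0.57). They were lower for mitosis (-0.49), DNA replication (-0.44), p53 targets (-0.18), microglia and macrophages (-0.48), lymphocytes (-1.38) and ER stress (-0.39). With an estimated correlation the adjusted p of these 16 lists ranged from 0.425 to 0.579, so 0 were called, and fry called 0.

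In the direct comparison limma called 1 gene (0 with edgeR, 173 with DESeq2, 1357 at an unadjusted p under 0.05). Of the 10 splits of these 6 libraries, 3 gave as many genes, and 10 splits cannot give a share under 0.05. The highest other split called 265 genes, which points to a structure of the samples. It set ETV5 replicate 1 with NPY replicates 1 and 3, whose cortex shares were 0.695, 0.770 and 0.814%, against the other 3 libraries.

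Ifi44l, H2-Eb1 and H2-T3 were higher in NPY-labelled than in control tumours. The tables argue against an interferon response for Ifi44l, since the other 20 measured interferon genes had a median log2 fold change of -0.36 (-0.75 to 0.29), and against a class II programme for H2-Eb1, since 6 other class II genes had a median of -0.12 (-0.55 to 0.31). For Ifi44l, 0 of 9 measured genes within 1 Mb were called in the same comparison, which decides nothing about a variant at the gene, so a strain variant and an effect of NPY cannot be told apart. At the MHC, the largest gaps of the H2-Eb1 to H2-Aa ratio and of H2-T3 put 6 of 9 tumour libraries on the same side, where the H2-T3 gap was set by 1 read in control replicate 3, and a second test by order, added after that outcome was seen, placed 9 of 9. ETV5 replicates 2 and 3, with no added NPY, had ratios of 0.592 and 0.698 and H2-T3 at 43 and 136 reads, beside 0.265 to 0.514 and 85 to 133 in NPY-labelled tumours, 0.0351 and 10 in ETV5 replicate 1 and at most 0.0144 and 12 in controls, so added NPY does not account for those 2 libraries and a strain variant at the MHC stays open.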

How the results depend on the processing

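The cortex share covariate, edgeR on recovered reads, TMM scaling and the other pseudocounts were chosen after the data were seen, and the other settings were planned. Against cortex the gene count stayed within 1.5 times of 10521 in each setting (9770 to 10894 with a replicate left out), and library totals moved the median of all genes by 0.17 on the log2 scale. The Etv5 rise there kept its call in each setting (1.04 to 1.30 with a replicate left out), and Npy (-2.32 to -1.82) lost its call in the fit with the library code prefix (-2.03), which took its spread from the ETV5 libraries as well. With an estimated correlation 0 lists were called in each of the 4 comparisons, and fry called 35, 0, 11 and 0 in the order cortex, ETV5, NPY, ETV5 against NPY. With a replicate left out, camera called 20 to 24, 16 to 28, 16 to 21 and 12 to 21 lists. For ETV5 against control tumours limma called 0 genes in each setting, DESeq2 called 76, and 7 lists were called with the cortex share in the fit. Etv5 ranged from 0.45 to 0.61 and Npy from -3.45 to -1.66 with a replicate left out. For NPY against control tumours the count was 1833 with DESeq2, 264 with the replicate block (250 shared with the 727), 1128 with the spread over all groups (587 shared), 0 with the library code prefix and 0 with the cortex share. It was 1 to 571 with a replicate left out. Npy was called with DESeq2 (-1.92) and without NPY replicate 3 (-2.96; -2.96 to -1.58 with a replicate left out), and Etv5 ranged from 0.05 to 0.28. For ETV5 against NPY the count was 0 with edgeR on recovered reads, edgeR with size factors of the DESeq2 type, the replicate block, the prefix or the cortex share, 173 with DESeq2, 5 with the spread over all groups, and 0 to 88 with a replicate left out. Etv5 ranged from 0.28 to 0.51 and Npy from -1.16 to 0.60. The overlap was 32 genes with DESeq2. With the prefix in the fit of NPY against control tumours, the median SE of the genes called lower rose from 0.348 to 1.08, and for the other changes the cause was not tested.

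With the cortex share in the fit, the direction of some results turned. For ETV5 the median of excitatory neurons became 0.029, which the construction sets near 0, as the share is computed from that list. Other medians became 0.067 for inhibitory neurons and 0.24 for glutamate and GABA receptors. The test direction also turned for astrocytes (median -0.0023), pan-neuronal genes (-0.11) and cholesterol synthesis (-0.015). For NPY they became 0.34 for oligodendrocyte precursors, 0.56 for p53 targets, -0.62 for hypoxia and glycolysis, -2.79 for lymphocytes and -2.24 for antigen presentation, and the test turned for homeostatic microglia (median -0.012), with Pnoc at 0.092 and H2-Eb1 at -2.02. The share did not overlap between NPY-labelled and control tumours, so that fit cannot separate the share from the group, and these NPY values decide nothing. With 1 library left out, list tests turned for astrocytes with ETV5 (-0.18 without ETV5 replicate 1), neurodevelopmental transcription factors with ETV5 (-0.0035 without ETV5 replicate 2), lymphocytes and antigen presentation with NPY (-0.82 and -0.64 without control replicate 3, and the lymphocyte median was 0.79 without control replicate 2) and oligodendrocyte precursors between ETV5 and NPY (-0.67 without ETV5 replicate 3). The cause was not tested. At these depths and this spread, 2.4% of 2-fold and 52.6% of 4-fold changes were recovered in simulated data of the ETV5 design, which limits what its count of 0 excludes.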

Other observations

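The tests of neuronal and astrocyte genes, of the library code and of Npy against other neuronal genes were chosen after the results were seen, as was the cortex share covariate, and the test of the other lower genes and the splits were not. Xist and Ddx3y were chosen after their values were seen. Xist, which is transcribed from the inactive X chromosome, stood at 0.403 CPM in cortex replicate 1, 0.741 in control replicate 1, 0.299 in ETV5 replicate 2, 0.177 in ETV5 replicate 3 and 0.486 in NPY replicate 1, where Ddx3y of the Y chromosome stood at 84.6, 87.5, 104, 124 and 106. In the other libraries Xist lay between 390.1 and 824 CPM and Ddx3y was at most 1.01. Rn45s ranged from 732 to 3943 CPM in cortex, 618 to 754 in control tumours, 1079 to 5503.5 in ETV5 tumours and 1461 to 5869 in NPY-labelled tumours.

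Genes lower in NPY-labelled tumours may reflect less cortical tissue in those samples. The difference in cortex share (8.69%) times the level in cortex accounted for a median of 1.17 of the fall of 26 neuronal genes (quartiles 0.986 to 1.45) and 0.824 of the fall of 569 other genes (0.421 to 1.17), of which 160 were under 0.5 and 48 stood above their cortex level in control tumours. The share is itself set by excitatory neuron genes, and the 26 neuronal genes were chosen because they were called lower. Their values therefore cannot tell less cortical tissue from another loss of neuronal transcripts. For 6 astrocyte genes the share difference accounted for 0.428 of the fall (0.263 to 0.468), under the 0.5 first set as the bound against less cortical tissue. That bound was dropped after the value was seen, since the share assumes the profile of normal cortex. Of these 6 genes, however, 5 were under 0.5 and 0 stood above their cortex level in control tumours. Gfap, at 2082 CPM in controls against 295 in cortex, was not among them. These 6 genes too were chosen because they were called lower, which favours large falls and so small accounted shares. Their values therefore cannot decide whether less cortical tissue is a full account of their fall. With the library code prefix in the fit, 0 of 622 genes stayed called by limma, as the median SE rose from 0.348 to 1.08 while the median log2 fold change went from -2.25 to -2.57, so the code series and the NPY group cannot be told apart. An effect of NPY itself stays open and untested.

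Npy was lower in ETV5 than in control tumours without passing (log2 fold change -2.54, adjusted p = 0.732), and the cortex share of the samples may account for part of it. With the share in the fit the log2 fold change was -0.79 (SE 0.32), or 31.2% of its size. The share is itself set by excitatory neuron genes, so that fit cannot tell less cortical tissue from a general fall of neuronal transcripts. Npy lay -1.31 SD from the mean of 20 other neuropeptide and inhibitory neuron genes (-1.33), and 0 of the 20 stood lower than Npy. A general fall of neuronal transcripts was therefore neither shown nor excluded as the account of the Npy value. An effect of ETV5 stays open and untested.

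Each of the other comparisons also has 10 splits of its 6 libraries, which cannot give a share under 0.05. Control tumours against cortex gave 10521 genes and the highest other split 0 (1 split as large, the real one). NPY-labelled against control tumours gave 727 and the highest other 0 (1 split as large). ETV5 against control tumours gave 0 with limma (76 with DESeq2, 944 at an unadjusted p under 0.05) and the highest other 6 (10 splits as large).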
